A study of Rattus norvegicus with 4 samples.

How the data were processed

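RNA from rat mammary gland was hybridised to 4 Affymetrix arrays, 1 for each group of SDR lactation, heterozygous HHR lactation, homozygous HHR lactation and SDR involution, each on day 1 per the labels. Per the labels' protocols, total RNA was extracted with a silica column kit and turned into biotinylated cRNA. The deposited values are MAS5 signals, an intensity per probe set on a linear scale, and MAS5 is named per the submitters' processing notes without a version. The authors' scaling was read from the values, because the mean after leaving out the lowest and highest 2% of probe sets was 500.0 in every array. Detection calls, saturation flags and the MAS5 parameters are not given in the sources used here. Columns were tied to samples by name and groups were taken from the labels, with 0 columns left unmapped.

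Each array held 31099 probe sets, of which 57 were controls. Per the platform annotation, 1 gene symbol was listed for 20832 probe sets, several for 436 and none for 9774, and only those with 1 symbol were named. Gene identifiers of 20764 probe sets were found in a RefSeq gene table of assembly GRCr8, used for names only, and 0 symbols needed updating. Values under the pooled 40th percentile of all probe sets (91.5) were raised to it before the log2 was taken. A gene was represented by its probe set with the highest mean floored log2 value over the 4 arrays, which gave 14217 genes, 11395 of them above the floor in at least 1 array. Of these genes 31.8% had several probe sets. The floor limits what can be seen of weakly expressed genes. The number of arrays limits the precision of every value.

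With 1 array per group no test was made and no error could be given. For each of 5 pairs of arrays, genes at least 2-fold higher and lower were counted among those above the floor in at least 1 of the pair. The overlap of 2 comparisons was set beside the product of their counts over the number of genes and, where both use the SDR lactation array, beside 100 simulations of unchanged groups that share it. Correlation and covariance were taken across genes. For each gene list the median log2 difference was given with its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression, where at least 5 members were measured. The design, the 29 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined.

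The lists were milk proteins, milk fat globule and fatty acid synthesis, cholesterol synthesis, lactose synthesis and milk secretion transporters, prolactin and Stat5 signalling, hormone-sensing cells, early involution and Stat3 pathway, acute phase and inflammation, extracellular proteases and their inhibitors, apoptosis, lysosome, unfolded protein and amino acid stress response, immediate early genes, cell cycle, interferon response, keratins of the type II cluster and tight junctions, and markers of adipocytes, luminal epithelium, myoepithelium, fibroblasts and matrix, endothelium, macrophages and neutrophils, T cells, B and plasma cells, skeletal muscle, red cells, nerve and Schwann cells, and skin epidermis. Of 587 entries 517 were on the array, some through an older symbol, so that the members Krt6c, Lce3b, Loricrin, Hba-a3 and Myl11 may be paralogs of the gene meant. Several genes belong to more than 1 list. The RT1 genes were grouped after their values were seen, and the clock genes after those of Nr1d1 and before those of the other members.

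Genes were named by 3 rules. The 10 largest differences in each direction were taken among genes at least 2-fold different with both values above the floor and all further probe sets in the same direction, and the 5 brightest among genes at the floor in 1 array of the pair. For heterozygous HHR against SDR these numbers were 5 and 3, and for homozygous HHR the smaller of the differences from SDR and from heterozygous HHR was ranked. From each list, up to 4 members past 2-fold and up to 2 short of it were eligible by brightness, and of these a selection is given. Placeholder symbols were left out, and 1 gene that these rules name is not reported here. Genes outside these rules are said to be so where they appear, apart from values of an already named gene repeated for another comparison.

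Alternatives were median centring and quantile normalization of the arrays, a floor at the 25th or 55th percentile, the floor added to each value as a pseudocount, the mean of all probe sets of a gene, the highest single probe set without shared-probe suffixes, a 3-fold threshold, and random lists without matching. The steps were tested on simulated data with the spread of the homozygous HHR and SDR pair. Of 50 planted genes at each size, 20% were recovered at 1.5-fold, 58% at 2-fold, 82% at 3-fold and 94% at 4-fold. Of the simulated genes 10943 were measured. The planted genes were drawn only from those above the floor in all 4 arrays, so the shares leave out genes at the floor in any array. Of 200 unshifted lists 3 fell at or beyond the 1st or 99th percentile. These lists held random genes with independent noise, so a share near that of the bounds was built in. Members of the real lists may vary together between animals, which the percentiles leave out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.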

Results

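Gene expression was measured in mammary gland RNA of 4 groups of rats with 1 array in each group. Sprague-Dawley rats (SDR) were sampled on day 1 of lactation and on day 1 of involution, the regression of the gland after milk removal stops. Hirosaki hairless rats (HHR), a hairless mutant strain, were sampled on day 1 of lactation as heterozygous and as homozygous animals. Each array held 31099 probe sets, and between 10368 genes (heterozygous HHR) and 10472 genes (SDR involution) lay above the floor signal of 91.5. There were no replicates, so no difference given here has a replicate error or a test, and differences are described by size. All signals and folds were computed with lower values raised to the floor, and a fold against a value at the floor is a lower bound.

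Checks of the arrays preceded the comparisons. The ratio of 3′ to 5′ signal of the Gapdh control probe sets, which grows with RNA degradation, was 1.17 in SDR lactation, 1.93 in heterozygous HHR, 2.30 in homozygous HHR and 1.60 in SDR involution. The same ratio for actin was 4.60, 7.87, 5.91 and 4.80 in that order. Both ratios were lowest in SDR lactation, for actin only slightly below SDR involution. Differences of HHR and of involution from SDR lactation may therefore hold an effect of RNA quality. Such an effect was not tested. The 14 brightest probe sets, which include milk protein genes, had median signals of 54367, 58869, 48815 and 43366. Their median log2 differences from SDR lactation were 0.03, -0.16 and -0.37, close to the 0.04, -0.13 and -0.46 of the spiked-in cre control, so differences of milk protein genes may be bounded by the upper end of the measured range.

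The comparison of homozygous HHR with SDR at lactation asked which genes differ in the mutant gland. Genes of the immediate early response, which are transcribed within minutes of a stimulus, were higher in homozygous HHR. Of the 21 measured members 9 were at least 2-fold higher and 0 lower, with a median log2 difference of 0.81 (percentile 100 among matched random lists). Myc, a growth regulator, was 6.84-fold higher, Fos was 5.09-fold higher and Jun was 4.82-fold higher, the latter pair forming the AP-1 transcription factor. Of single genes, Cd36, a fatty acid translocase, had 4.36-fold lower signal (7958 against 34685), and Atp2b2, the plasma membrane pump that moves calcium into milk, had 4.65-fold lower signal (386 against 1794).

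In all, 410 genes were at least 2-fold higher and 296 at least 2-fold lower in homozygous HHR, 6.50% of 10866 measured genes. Simulated arrays with the spread of this pair gave 511 of 10724 unchanged genes (4.77%) past 2-fold, but that spread includes the real differences of the pair, so the share is near the observed one in part by construction. With the mean of all probe sets of a gene the counts were 301 and 306, which turned which direction was larger. Among called genes with a further probe set above the floor, 117 of 165 had all probe sets in the same direction. Of the gene lists, 9 of 27 lay at or beyond the 1st or 99th percentile.

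Acute phase and inflammation genes were higher in homozygous HHR, with 8 of 19 measured members at least 2-fold higher, 1 lower and a median of 0.38 (percentile 99.9). The neutrophil chemokine Cxcl1 was at least 13.0-fold higher, the innate immune receptor Tlr2 was 4.31-fold higher and Cd14, a receptor for bacterial lipopolysaccharide, was 2.76-fold higher, whereas the protease inhibitor Slpi was 5.27-fold lower. In the list of early involution and Stat3 pathway genes, 5 of 22 were higher and 1 lower, with a median of 0.22 (percentile 98.7). Cebpd, a transcription factor induced early in involution, was 8.94-fold higher, and Tgfb3, a growth factor of the regressing gland, was 2.18-fold higher. Igfbp5, which binds insulin-like growth factors, was 2.16-fold higher. Stat3 itself was 3.18-fold higher.

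Interferon response genes were lower, with 4 of 22 at least 2-fold lower, 0 higher and a median of -0.59 (percentile 0). The T cell chemokine Cxcl9 was 7.81-fold lower and the immunoproteasome subunit Psmb8 was 2.29-fold lower. In the list of the unfolded protein and amino acid stress response 3 of 22 members were lower and 1 higher, with a median of -0.26 (percentile 0.98). Atf4, its central transcription factor, was 2.03-fold lower and Phgdh, the first enzyme of serine synthesis, was 2.62-fold lower, while Atf3 was 4.73-fold higher. No list member reached 2-fold among 28 cell cycle genes, although their median was 0.34 (percentile 99.9).

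In the milk fat globule and fatty acid synthesis list 4 of 29 were lower, 0 higher and the median was -0.23 (percentile 2.62). Thrsp, a regulator of lipogenesis, was 2.41-fold lower, and Xdh, a fat globule membrane protein, had 33702 against 35936. Of the lactose synthesis and milk secretion transporters 4 of 25 were lower and 1 higher (median -0.20, percentile 4.61). The folate receptor Folr1 was 2.90-fold lower and the chloride cotransporter Slc12a2 was 2.40-fold higher. Only Spp1, an extracellular phosphoprotein, passed 2-fold among 9 milk protein genes, with 183 in SDR and a value at the floor in homozygous HHR. The casein Csn3 had 53588 against 60152. None of 19 cholesterol synthesis genes passed 2-fold (median -0.12). Among 15 genes of prolactin and Stat5 signalling 1 was higher, the feedback inhibitor Cish, at 3.17-fold, and the prolactin receptor Prlr had 12461 against 12407.

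Markers of cell types were also compared. Myoepithelial markers had a median of 0.60 (percentile 100), with 3 of 14 higher, among them the basal keratins Krt5 at 2.12-fold and Krt14 at 2.22-fold, and 2 lower. Endothelial markers had a median of -0.55 (percentile 0.03), with 3 of 13 lower, including the endothelial claudin Cldn5 at 3.41-fold, and 0 higher. T cell markers had a median of -0.38 (percentile 0.27), with 2 of 14 lower, among them the chemokine Ccl5 at 2.34-fold. Of the measured keratins of the type II cluster 3 of 5 were higher (median 1.04, percentile 99.99), Krt7 at least 3.94-fold. Adipocyte markers had a median of 0.27 (percentile 97.98), although 3 of 17 were at least 2-fold lower and 1 higher. The fatty acid binding protein Fabp4 was 2.42-fold lower. Red cell markers had 2 of 4 lower, with the haemoglobin gene Hbb 2.09-fold lower. Macrophage and neutrophil markers had 2 of 18 higher and 2 lower, with the calcium-binding S100a8 at least 3.55-fold higher. Nerve and Schwann cell markers had 2 of 6 lower, B and plasma cell markers 1 of 6 lower, and skin epidermis markers 1 of 5 higher. No member passed 2-fold among 14 luminal epithelial, 20 fibroblast and matrix, and 4 skeletal muscle markers, or among 5 markers of hormone-sensing cells. The same held for 23 lysosome, 19 apoptosis and 10 tight junction genes and for 19 extracellular proteases and their inhibitors.

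Heterozygous HHR were compared with SDR at lactation to show what the mutant strain shares without the homozygous state. Cell cycle genes were higher in heterozygous HHR, with 23 of 28 at least 2-fold higher, 0 lower and a median of 1.52 (percentile 100). Mki67, a proliferation marker, had 10701 against 2496 and was 4.29-fold higher, Top2a, the topoisomerase of dividing cells, was 4.63-fold higher, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was 4.41-fold higher. Interferon response genes were lower, with 8 of 22 at least 2-fold lower and a median of -0.91 (percentile 0). Irf7, a transcription factor of the interferon response, was 3.11-fold lower and Cxcl9 was 7.81-fold lower.

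The counts were 498 genes higher and 451 lower, 8.73% of 10876, and with the mean of all probe sets of a gene they were 407 and 447, which turned which direction was larger. In homozygous HHR 116 of the 498 higher genes were also higher and 153 of the 451 lower genes also lower, and 4 genes went opposite ways. Independent lists would share 29.6 in the same direction, and 62.1 came from simulated unchanged groups that share the SDR array. As that array enters both differences, part of the excess may come from it. Of the genes above the floor in both arrays the largest increase was that of Fam111a, 23.3-fold higher in heterozygous and 16.6-fold higher in homozygous HHR. Gdap1, a mitochondrial outer membrane protein, was 7.30-fold higher, the coagulation factor F5 was 6.55-fold higher, the cell cycle factor E2f8 was 5.83-fold higher and the DNA damage mediator Mdc1 was 5.78-fold higher. Sptbn4, a spectrin, had 915 against a value at the floor and Troap, a spindle protein, was at least 9.54-fold higher. The secretoglobin pseudogene Scgb1d2-ps1 was 26.8-fold lower, and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, was 7.79-fold lower. Cwc25, a splicing factor, was at least 4.73-fold lower, Entr1 at least 4.56-fold lower and the nuclease Dnase1l3 at least 4.46-fold lower. Genes of RT1, the rat major histocompatibility complex, went both ways, with 10 of 17 at least 2-fold lower and 3 higher. RT1-CE5 had 151 against 16488, 109-fold lower, and RT1-CE10 was 15.1-fold lower. For RT1-Ba, a class II gene, 1 probe set was at least 6.98-fold higher while another had a log2 difference of -6.50, so it has no settled direction. RT1 genes form a family of near-identical members, which probe sets may not tell apart, so their values are uncertain.

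Fibroblast and matrix markers were lower in heterozygous HHR, with 3 of 20 past 2-fold and a median of -0.51 (percentile 0), among them Fn1, fibronectin, at 2.27-fold. Endothelial markers had a median of -0.62 (percentile 0) with 2 of 13 lower, and macrophage and neutrophil markers one of -0.47 (percentile 0.03) with 5 of 19 lower and 2 higher. C1qa, a complement component of macrophages, was 2.33-fold lower. T cell markers had a median of -0.39 (percentile 1.09) with 2 of 13 lower, and red cell markers one of -0.96 with 2 of 4 lower, Hbb at 3.25-fold. Myoepithelial markers had a median of 0.68 (percentile 100), with Krt5 2.59-fold higher. In the early involution and Stat3 pathway list 5 of 21 were lower, 0 higher and the median was -0.40 (percentile 0.12), and the secreted chaperone Clu was 2.84-fold lower. The medians stand for the sampled tissue and do not separate a change in cell share from a change within cells.

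Between homozygous and heterozygous HHR, cell cycle genes were lower in the homozygous gland, with 20 of 28 at least 2-fold lower, 0 higher and a median of -1.21 (percentile 0). Mki67 was 2.64-fold lower and Ube2c was 3.76-fold lower. Immediate early genes were higher, with 10 of 21 past 2-fold and a median of 0.78 (percentile 100), including Klf6, a zinc finger factor, at 4.89-fold. Early involution and Stat3 pathway genes were higher, with 8 of 22 past 2-fold, 0 lower and a median of 0.56 (percentile 100). Cd14 was 3.64-fold higher, the antibacterial lipocalin Lcn2 was 2.11-fold higher and Ctsl, a lysosomal protease, was 2.07-fold higher. In SDR lactation Lcn2 had 25616 and Ctsl 8308, against 15836 and 3950 in heterozygous and 33408 and 8175 in homozygous HHR. Against SDR the early involution and Stat3 pathway list lay at percentile 98.7 in homozygous and 0.12 in heterozygous HHR. Part of its difference between them may thus be a low level in the heterozygous array.

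In total 409 genes were higher and 341 lower, 6.90% of 10877. Acute phase and inflammation genes had 7 of 20 higher (median 0.45, percentile 99.96), and Lbp, which binds lipopolysaccharide, was 2.36-fold higher. Extracellular proteases and their inhibitors had a median of 0.50 (percentile 99.98), with the plasminogen activator Plat 2.22-fold higher. Lysosome genes had a median of 0.31 (percentile 99.95) with 1 of 23 past 2-fold, luminal epithelial markers 0.53 (percentile 99.99) with 1 of 14, fibroblast and matrix markers 0.42 (percentile 99.98) with 3 of 20, and macrophage and neutrophil markers 0.42 (percentile 99.9) with 0 of 19. Against SDR these 4 lists lay at percentiles 40.1, 67.6, 71.6 and 6.66 in homozygous HHR and at 2.48, 1.77, 0 and 0.03 in heterozygous HHR, in that order. Extracellular proteases lay at 32.3 and 1.31. Mcl1, a survival factor of the Bcl2 family, was 2.82-fold higher and the tight junction claudin Cldn4 was 2.86-fold higher. Abcg2, a transporter that secretes riboflavin and drugs into milk, was 3.18-fold lower and the cell cycle driver Ccnd1 was 2.16-fold lower.

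Genes that differed at least 2-fold in homozygous HHR from both other lactation arrays numbered 163 higher and 38 lower. The higher genes were led by Foxq1, a forkhead transcription factor, at 8.19-fold over the nearer of the other 2 arrays, and by Ccn2, connective tissue growth factor, at 8.17-fold. Pdk4, an inhibitor of pyruvate dehydrogenase, was 7.40-fold higher and Cebpd 6.12-fold higher. The lower genes were led by Atp2b2 at 4.65-fold and C2cd4b at 4.60-fold. From the lists, 8 immediate early genes, 5 early involution and Stat3 pathway genes and 5 acute phase genes were among the higher ones.

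Further genes higher than in both were Anxa1, an annexin of the anti-inflammatory response, at 5.47-fold, the arrestin family member Arrdc4 at 4.93-fold, Jun at 4.82-fold, Rnf122 at 4.56-fold and the carnosine dipeptidase Cndp1 at 4.41-fold. Ephx2, soluble epoxide hydrolase, was at the floor in both other arrays and at least 10.2-fold higher. Unc80 was at least 3.03-fold, Vtcn1 at least 2.53-fold, Maff at least 2.49-fold and Grm8 at least 2.41-fold higher, and for Grm8 another probe set went the opposite way. Genes lower than in both included Frem3 at 3.35-fold, the adenylyl cyclase Adcy4 at 2.89-fold, the oxysterol binding protein Osbpl1a at 2.88-fold, the calcium-binding oncomodulin gene Ocm at 2.65-fold, Rrp8 at 2.61-fold, the lysophospholipid transporter Mfsd2a at 2.53-fold, Spink8 at 2.42-fold and Trmt61a at 2.42-fold. At the floor in homozygous HHR were Gtse1, at least 3.46-fold lower, the ephrin receptor Epha2, at least 2.58-fold, Rgs19, at least 2.36-fold, Agps, at least 2.34-fold, and Nudt13, at least 2.30-fold. With the floor raised to the 55th percentile Frem3, Adcy4 and all named genes at the floor in this set except Ephx2 no longer passed 2-fold.

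**Figure D1:**
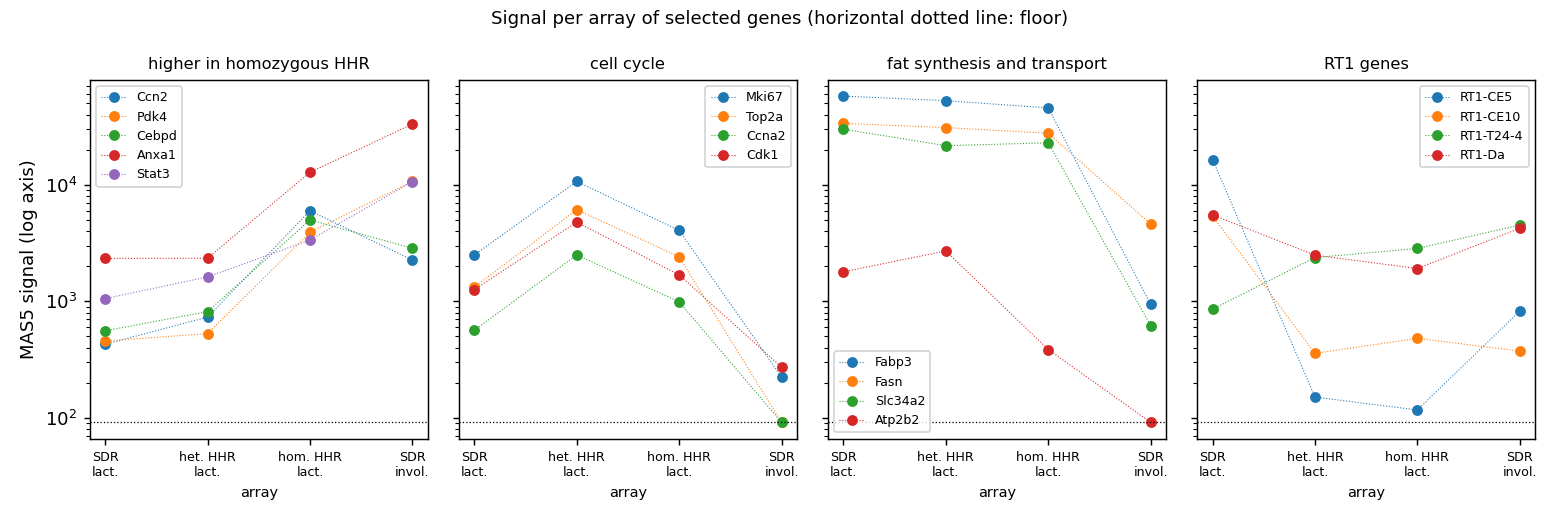
MAS5 signal on a log axis for selected genes in each of the 4 arrays, with 1 point per gene and array, dotted guides joining the points of a gene, and a horizontal dotted line at the floor of 91.5. Pdk4 and Anxa1 were higher in homozygous HHR and in SDR involution than in the other 2 arrays, Mki67 was highest in heterozygous HHR (10701), and Fabp3 was 45740 or more in the lactation arrays against 941 in involution.

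Involution was compared with lactation in SDR. The labels do not give the length of lactation before involution. An effect of the end of milk removal therefore cannot be told apart from one of the stage of lactation. Genes of milk fat synthesis were lower in involution, with 19 of 29 at least 2-fold lower, 0 higher and a median of -1.75 (percentile 0). Fabp3, a fatty acid binding protein, was 61.4-fold lower (its lactation signal was among the brightest, so this may be a lower bound), Cd36 was 23.0-fold lower, Fasn, fatty acid synthase, was 7.32-fold lower, and Lpl, which frees fatty acids from lipoproteins, was 11.4-fold lower. Cell cycle genes were lower, with 20 of 28 past 2-fold and a median of -2.32 (percentile 0), Mki67 at 11.2-fold. Acute phase and inflammation genes were higher, with 12 of 19 past 2-fold and 0 lower (percentile 100), among them complement C3 at 3.52-fold. In the early involution and Stat3 pathway list 8 of 22 were higher and 0 lower (median 0.79, percentile 100), and Stat3 was 10.1-fold higher.

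The counts were 1129 genes higher and 985 lower, 19.2% of 11014, the highest share of the comparisons against SDR lactation. With arrays centred on their medians the counts were 978 and 1115, after quantile normalization 1044 and 1046, and with the mean of all probe sets 887 and 925, each of which turned which direction was larger. Lists with medians at or beyond the 1st or 99th percentile numbered 15 of 28.

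Milk secretion genes were lower in involution as well. Among lactose synthesis and milk secretion transporters 12 of 25 were lower and 3 higher (median -0.82, percentile 0.01). The phosphate transporter Slc34a2 was 48.7-fold lower, the galactosyltransferase B4galt1, which makes lactose, 8.52-fold lower, and Atp2b2 at least 19.6-fold lower. Cholesterol synthesis genes had 9 of 19 lower (median -0.79, percentile 0.01), with Insig1, a sterol sensor, 11.2-fold lower. Prolactin and Stat5 signalling genes had 6 of 14 lower (median -0.93, percentile 0.05), with Elf5, a factor of secretory cells, at 3420 against 13668 and Prlr 2.91-fold lower. Adipocyte markers had 8 of 17 lower (percentile 0.01), of which Lpl is also a gene of the milk fat list. Milk protein genes had 1 of 10 higher and 2 lower, and Csn3 had 46227 against 60152.

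Genes higher in involution included Timp1, an inhibitor of matrix proteases, at 8593 against 781, and 9 of 20 apoptosis genes (median 0.69, percentile 99.95), among them the stress gene Gadd45a at 5.32-fold. Type II cluster keratins had 5 of 8 higher (median 1.65, percentile 100), with Krt8 at 4.37-fold and Krt7 at least 50.5-fold. Skin epidermis markers had 5 of 8 higher (median 1.22, percentile 100), led by Sbsn, suprabasin, at 28.3-fold. Interferon response genes had 7 of 22 higher and 1 lower (median 0.70, percentile 99.85), with Irf1 3.05-fold higher and Cxcl9 5.67-fold lower. S100a8 was at least 30.7-fold higher, and 2 of 19 macrophage and neutrophil markers were higher and 1 lower. Immediate early genes had 6 of 21 higher (median 0.77, percentile 100), with Fos at 5.44-fold. Red cell markers had 3 of 3 lower, with Hbb 4.23-fold lower. T cell markers had a median of -0.55 (percentile 0.05) and endothelial markers one of -0.53 (percentile 0.48), with Kdr, a receptor of vascular endothelial growth factor, at 597 against 3286. Endothelial, T cell and red cell medians were lower than in SDR lactation in every other array. Between homozygous and heterozygous HHR they were 0.09, -0.135 and 0.10 in that order. For these lists an SDR lactation array that stands apart cannot be told from changes in the other groups. The same holds for single genes lower than SDR lactation in every other array, among them Cxcl9, Folr1, Psmb8 and Fabp4. Cxcl9 had 3051 in SDR lactation and 391, 391 and 538 in heterozygous HHR, homozygous HHR and involution. Folr1 had 12549 in SDR lactation and 3841, 4323 and 4738 in the others, in that order.

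Other large increases were in Dmkn at 28.1-fold, Pdk4 at 23.5-fold, the metallothionein gene Mt2A at 22.6-fold, Sdr16c5 at 21.6-fold, the lipase inhibitor Angptl4 at 21.2-fold, Wfdc2 at 20.1-fold, the ubiquitin-like Ubd at 18.3-fold, C3h15orf48 at 17.2-fold and Pdlim5 at 15.9-fold. Card14, a scaffold of NF-kappaB signalling, was at least 138-fold higher, Sdcbp2 at least 46.9-fold and the cadherin family gene Cdhr1 at least 44.8-fold. Other large decreases were in Scgb1d2-ps1 at 205-fold, Prr27 at 149-fold, the matricellular Ccn3 at 37.9-fold, the nucleoside transporter Slc28a3 at 37.5-fold, the peptide hormone gene Apln at 33.5-fold, the lipase inhibitor G0s2 at 28.3-fold, the water channel Aqp3 at 27.7-fold and the carbonic anhydrase Car2 at 26.0-fold. C2cd4b was at least 79.7-fold lower and Top2a at least 14.4-fold lower. RT1 genes went both ways: RT1-CE16 was at least 33.5-fold lower, RT1-Bb at least 29.9-fold lower and RT1-Ba at least 37.1-fold higher, and other probe sets of RT1-Bb and RT1-Ba went the opposite way.

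The difference between homozygous and heterozygous HHR was set against that between involution and lactation, which use different arrays. The genes past 2-fold in the same direction in both numbered 252, of which 146 were higher and 106 lower, and 42 went opposite ways. Independent lists of these sizes would share 70. The 106 lower genes held 18 cell cycle genes, among them Mki67, Top2a and Cdk1, the kinase that starts mitosis. In homozygous HHR against SDR lactation, however, 0 of 28 cell cycle genes were lower and their median was 0.34, with Mki67 at 4059 against 2496. The 146 higher genes held 6 of the early involution and Stat3 pathway list (Stat3, Cebpd, Igfbp5, Ctsl, Cd14 and Lbp) and 5 immediate early genes, Fos among them. Of these, Ctsl and Lbp were lower in heterozygous HHR than in SDR lactation, 2.10-fold and 2.19-fold, and had 8175 against 8308 and 5370 against 4982 in homozygous HHR against SDR. Across 11395 genes, which are not independent replicates, r was 0.22 and the covariance 0.102.

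**Figure D2:**
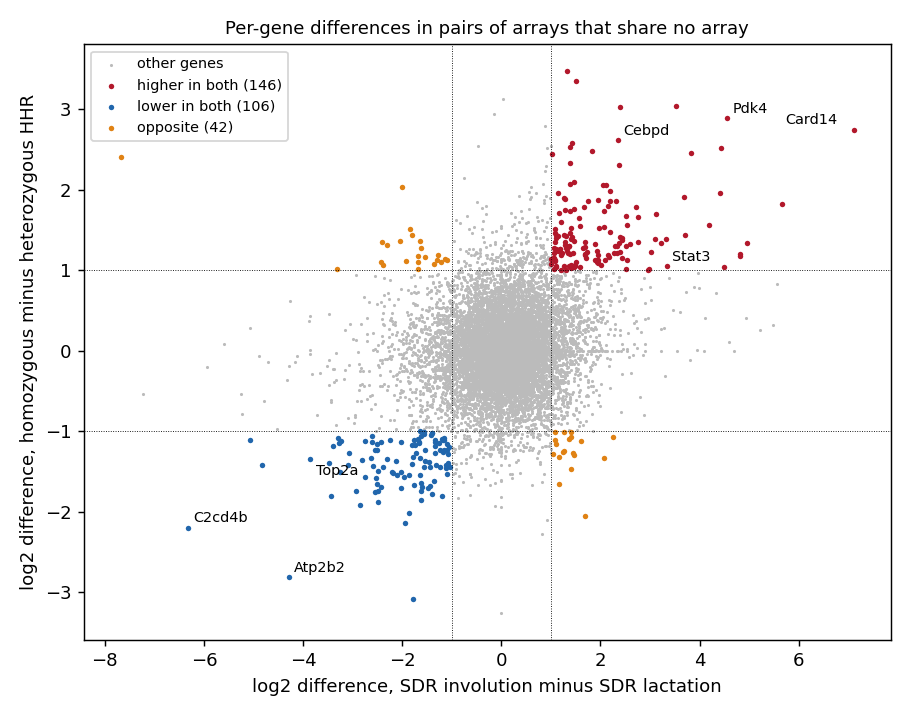
Log2 difference between homozygous and heterozygous HHR (vertical axis) against that between SDR involution and SDR lactation (horizontal axis), with 1 point per gene, dotted lines at 2-fold and coloured points for the 146 genes higher in both, the 106 lower in both and the 42 of opposite direction. Pdk4, Cebpd and Card14 lie at the upper right and Atp2b2 and C2cd4b at the lower left.

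Homozygous HHR against SDR and involution against lactation shared 366 genes past 2-fold in the same direction, with 218 higher, 148 lower and 13 opposite. Independent lists would share 66.2, and 62.1 came from simulated unchanged groups with a common SDR lactation array, over 100 simulations. The simulation took its spread from the homozygous HHR and SDR pair for every overlap and held no effects, and the independent number leaves out the common array, so neither is a full baseline. As that array enters both differences, part of the excess may come from it. The covariance was 0.224 against 0.0962 simulated, a difference of 0.127, and r was 0.48 against 0.50 simulated. For heterozygous HHR the difference of covariances was 0.0258, with 260 genes in the same direction and 109 opposite. The gap between homozygous and heterozygous HHR is by construction the covariance of 0.102 given above. It is therefore not a further result, and the medians that follow draw on the same differences. The 1129 genes higher in involution had a median log2 difference from SDR lactation of 0.44 in homozygous and 0.21 in heterozygous HHR, and the 985 lower genes -0.37 and -0.28. Between homozygous and heterozygous HHR, a comparison that shares no array with the choice of these genes, the medians were 0.22 and -0.12, with 63.4% and 60% of the genes in the direction of involution. Of the 163 genes higher in homozygous HHR than in both other lactation arrays, 93 were also higher in involution and 1 was lower. Of the 38 lower ones, 20 were also lower in involution and 0 higher. The SDR lactation array enters both choices, so part of this may come from it, and no value for unchanged groups was computed.

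Homozygous HHR at lactation were finally compared with SDR involution. These arrays differ in genotype and in stage at once, so a difference between them cannot be assigned to either from this pair alone. Milk fat genes were higher in homozygous HHR, with 18 of 29 past 2-fold, 0 lower and a median of 1.49 (percentile 100). Fabp3 was 48.6-fold higher, possibly a lower bound as its signal was among the brightest, and the desaturase gene Fads1 was 16.1-fold higher. Cell cycle genes were higher, with 20 of 28 past 2-fold and a median of 2.46 (percentile 100), Mki67 at 18.2-fold and Nusap1, a spindle protein, at 17.9-fold. Acute phase and inflammation genes were lower, with 10 of 21 past 2-fold and 2 higher (percentile 0), and interferon response genes had 14 of 22 lower and a median of -1.39 (percentile 0). Stat3 was 3.17-fold lower than in involution, and Myc was 12.2-fold higher.

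In total 844 genes were higher and 853 lower, 15.4% of 10998. The counts were 941 and 749 with arrays centred on their medians and 920 and 804 after quantile normalization. They were 676 and 638 with the floor at the 55th percentile, 686 and 608 with it as a pseudocount and 327 and 241 at 3-fold. Each of these turned which direction was larger. Prolactin and Stat5 signalling genes had 6 of 14 higher (median 0.97, percentile 99.99), with Elf5 3.18-fold higher, and apoptosis genes 8 of 20 lower (median -0.60, percentile 0.11), with Gadd45a 6.26-fold lower. Prr27 was 158-fold higher, Fam111a 82.1-fold, Scgb1d2-ps1 40.4-fold, Slc34a2 37.2-fold, the lysine catabolic enzyme gene Aass 25.7-fold, Car2 19.8-fold, G0s2 18.5-fold and Ccn3 18.5-fold. Fam111a had 10912 in homozygous HHR but only 658.5 in SDR lactation and 132.9 in involution, whereas Prr27 had 29696, 28013 and 187 in that order. At the floor in involution were Top2a, at least 26.4-fold higher, Ect2, at least 16.7-fold, Spc24, at least 13.3-fold, Pcdh17, at least 12.4-fold, and the cyclin gene Ccna2, at least 10.8-fold. Lower in homozygous HHR were Cdhr1 at 35.8-fold, Sdcbp2 at 22.9-fold, Krt7 at 12.8-fold, C3h15orf48 at 12.6-fold, Vtcn1 at 12.3-fold, Urah at 11.7-fold, Card14 at 11.5-fold, Sbsn at 11.2-fold, Timp1 with 779 against 8593 and Tspan1 at 10.7-fold. At the floor in homozygous HHR were Gpr15lg, at least 25.9-fold lower, the antibacterial lectin gene Reg3b, at least 17.0-fold, Tnnt2, at least 14.0-fold, the retinaldehyde dehydrogenase Aldh1a3, at least 11.6-fold, and Wnt5b, at least 9.76-fold.

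**Figure D3:**
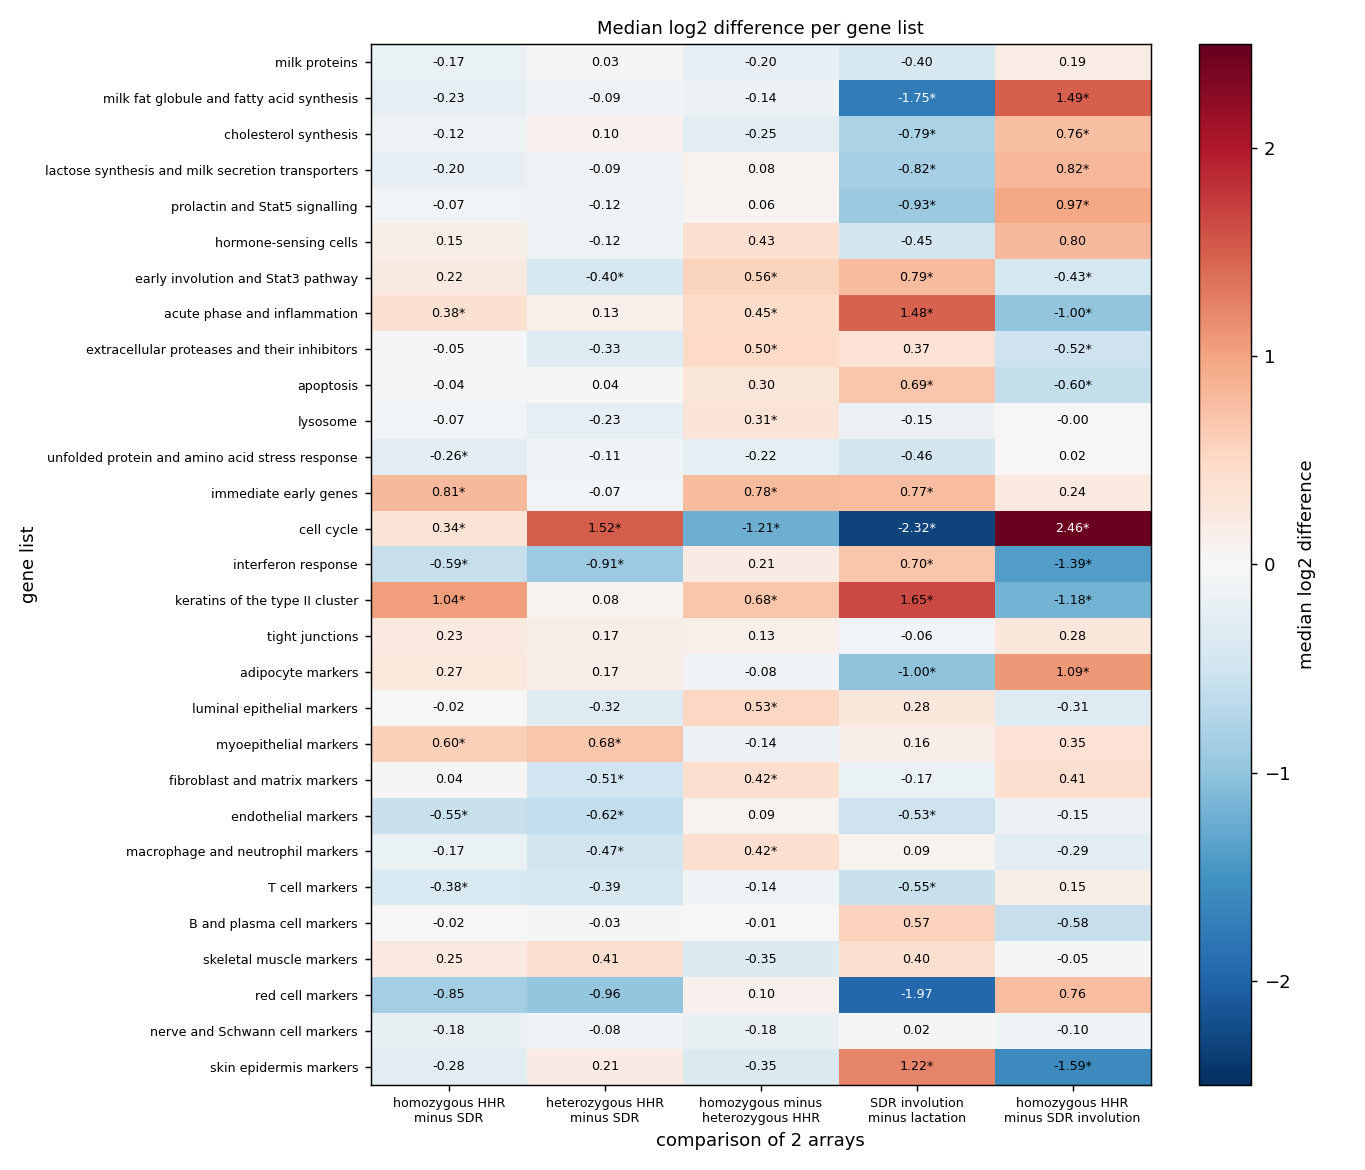
Median log2 difference of each of the 29 gene lists (vertical axis) in each of the 5 comparisons of 2 arrays (horizontal axis), coloured from blue (lower) to red (higher), with asterisks at medians at or beyond the 1st or 99th percentile among 10000 matched random lists. The cell cycle list runs from -2.32 in involution against lactation to 2.46 in homozygous HHR against involution.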

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

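All alternatives were chosen before the data were examined. Of 112 recomputed counts 81 stayed within 1.5 times the reported value. List medians were recomputed only for the 54 of 137 at or beyond the 1st or 99th percentile. Whether each stayed beyond those bounds is not given here. Of their 378 values 331 were within 1 standard deviation of the random-list medians from the reported value. A further 46 moved (32 nearer to 0 and 14 further from it) and 1 reversed. Those that moved were 16 with the mean of all probe sets, 10 with the pseudocount, 10 and 8 with the floor at the 55th and 25th percentile and 2 after quantile normalization. By list they were 7 each of immediate early and of acute phase genes, 6 of cell cycle, 4 of T cell markers, 3 each of apoptosis, interferon response and type II cluster keratins, 2 each of the early involution, milk fat, cholesterol synthesis, protease and skin epidermis lists and 1 each of fibroblast, myoepithelial and prolactin signalling lists. Of 742 values of named genes 720 kept direction and threshold, 18 no longer passed 2-fold and 4 reversed. These genes were chosen for large differences, so that most kept their direction follows in part from the choice. Neither median centring nor quantile normalization moved a count by over 1.5 times. A lower or higher floor changes how many weak signals can be called, and a stricter threshold how many genes pass, by construction. With the floor at the 25th percentile, homozygous HHR against SDR gave 652 higher and 507 lower, heterozygous HHR against SDR 756 and 689, homozygous against heterozygous HHR 637 and 551, the set different from both 366, and the overlap of homozygous HHR against SDR with involution 567. With it at the 55th, the lower counts were 191 for homozygous and 297 for heterozygous HHR against SDR. With the floor as a pseudocount the 3 lactation comparisons gave 261 and 197, 324 and 261, and 261 and 217, the set different from both 127 and that overlap 228. At 3-fold the 5 comparisons gave 100 and 51, 130 and 84, 86 and 44, 345 and 400 (involution against lactation), and 327 and 241 (homozygous HHR against involution), the set different from both 42, and the overlaps with involution 45 (homozygous against heterozygous HHR) and 73 (homozygous HHR against SDR). The median of type II cluster keratins between homozygous and heterozygous HHR was 0.68 in the main setting. It was -0.056 with the floor at the 25th percentile, and the cause was not tested. RT1-Ba reversed with the probe set: -2.40 as a mean and -6.50 for the single probe set in heterozygous HHR against SDR, and -1.80 and -4.73 in involution against lactation. No paired analysis was possible because each group had 1 array. Signals near the floor limit the rest.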

Other observations

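Tests chosen after the result was seen were those of scaling, RNA degradation, RT1 alleles and joint RT1 change and the split by direction of the test of the heterozygous array; the undivided test of that array and that of time of day were written before their results were seen. RT1 genes, which encode the major histocompatibility complex, stood apart in comparisons with SDR lactation and between homozygous HHR and SDR involution. Of 18 measured RT1 genes 9 were at least 2-fold lower and 3 higher in homozygous HHR, 10 of 17 lower and 3 higher in heterozygous HHR, and 6 higher and 4 lower in SDR involution. Against SDR involution, 9 of 18 were at least 2-fold lower and 2 higher in homozygous HHR. Homozygous and heterozygous HHR differed in 1 of 18. RT1-CE5 had 16488 in SDR lactation, 151 and 117 in heterozygous and homozygous HHR and 825 in involution, while RT1-A was at the floor in SDR lactation and had 2205 in involution. The set of RT1 genes, and RT1 genes other than those in the comparisons above, were chosen after their values were seen, as was Nr1d1 below.

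The first pattern weighed was the set of 252 genes shared by homozygous against heterozygous HHR and involution against lactation. Under median centring and quantile normalization 251 and 260 genes were shared, at least 3.64 times the independent number. This argues against scaling as the cause. Median log2 differences were already -0.0009 between homozygous and heterozygous HHR and 0.0797 between involution and lactation. Median centring could therefore change little, and its count adds little weight. A heterozygous array standing apart on its own cannot be told apart for the genes higher in both: 128 of 146 (87.7%), and 169 of all 252 (67.1%), differed by less than 2-fold between heterozygous HHR and SDR lactation, but the bound of 50% set before was wrong, since 91.7% of 11395 genes met it and the SDR lactation array enters both the choice of genes and this test. Of the lower genes only 41 of 106 (38.7%) did, so that part, with its 18 cell cycle genes, may be a high level in the heterozygous array. Of the higher genes 93 were also at least 2-fold higher in homozygous HHR than in SDR lactation. These are the same 93 genes as in the Results. The SDR lactation array enters their choice and this count, so the count does not set the higher genes apart. Other higher genes, such as Ctsl and Lbp, were lower in heterozygous HHR alone. RNA degradation cannot be told apart, as log2 differences of the 3′ to 5′ ratio were 0.25 and 0.45 for Gapdh but -0.413 and 0.06 for actin, none of them reaching 2-fold either way. A partial involution-like state of the homozygous gland, the biological alternative, was not tested; it stays open for the genes higher in both, while cell cycle genes go against it in the lower part, with 0 of 28 lower and a median of 0.34 in homozygous HHR against SDR lactation, and with 1 animal or pool per group differences between individuals stay open.

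The second pattern was RT1 genes of opposite direction. Different RT1 alleles in the sampled animals are a candidate explanation that cannot be told apart from others: the median absolute difference of RT1 genes lay at percentile 99.97 or higher among matched random lists in all 3 comparisons with SDR lactation, but the genes were grouped because they were seen to differ, so this restates the pattern. A joint change of antigen presentation genes stays open too: 3 probe sets were at least 4-fold higher and 8 at least 4-fold lower of 29 between the SDR arrays, but opposite directions are the pattern itself, and the bound of 3 was set with related counts known, after 2 earlier forms of this test were set aside. If alleles differ, the SDR lactation and involution animals differ in genotype as well as stage, and sequence was not analysed here.

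The last pattern was low signal of Nr1d1, a clock repressor, with 788 in SDR lactation, 893 in involution, 200 in heterozygous and 97.5 in homozygous HHR. If another time of day at collection were the source, clock genes in phase with Nr1d1 would be lower in both HHR arrays. This was written when the values of Nr1d1 alone had been seen. As a set they were not lower, with medians of 0.02 in homozygous and 0.393 in heterozygous HHR. The test cannot decide, because its 8 members ranged from -0.68 (Bhlhe41) to 1.92 (Per2) in heterozygous HHR. The list also mixed genes that peak at different hours, a reason found after the values were seen. In homozygous and heterozygous HHR, Dbp (-1.02 and -0.19) and Nr1d2 (-0.37 and -0.22) were lower. Per1 (1.05 and 1.39), Per2 (0.86 and 1.92) and Per3 (0.29 and 1.36) were higher, while Tef, Hlf and Bhlhe41 were mixed. The antiphase medians were -0.14 and -0.63. Clock genes also differed between SDR involution and lactation, among them Bmal1 (-1.85), Npas2 (-1.28) and Bhlhe41 (2.54). No biological explanation was tested.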
